A study of Mus musculus with 8 samples.

How the data were processed

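RNA was measured in 8 samples of mouse distal colon epithelium, 4 taken from the surface and 4 from the base of the crypts by laser capture microdissection. The mice were male C57BL/6 animals of 10 to 12 weeks. Per the labels' protocols, the RNA was amplified in a pair of successive rounds and then labelled with biotin for Illumina bead arrays. Per the series' design text, each of 4 mice gave a surface sample and a crypt base sample.

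The deposited log2 values cover 46632 probes on the 8 arrays. GenomeStudio is named in the submitters' processing notes, with no version, and the step that normalized the values is not given in the sources used here. At 99.0% of ranks the 8 sorted columns lay within 0.01 of each other, so the arrays had already been made equal in distribution. The array medians were 5.31 on the log2 scale, and the median linear signal was 39.7. The sources used here do not state whether background had been subtracted, and the values do not settle it. A further deposited table holds a signal and a detection p-value for each probe and array, per the file headers, in 46643 rows, with 11 probes listed more than once. Its 8 signal columns have names that match no sample's labels and were not used as samples. Over probes listed once, the log2 of each of these 8 columns equalled exactly 1 column of the log2 values within 1e-06, so this table holds normalized values too. The deposited detection p-values were used only as the number of arrays, of 8, on which a probe had a p under 0.05. Between 15041 and 16429 probes were detected per array, which is 32.3% to 35.2%. As many probe and array pairs exceeded a log2 signal of 5.52 (a linear signal of 45.8) as had a detection p under 0.05, and 98.0% of the pairs lay on the same side of both limits. That level is called background here. In 764 of the genes tested, all 8 signals exceeded it although the detection p was not under 0.05 on every array. Where a signal is near it, a fold change understates the difference. The number of arrays limits the precision of every value.

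Gene names came from the platform's probe annotation. It gave 1 gene symbol to 29976 probes, several to 10 and none to 16646, and 29921 of the probes with 1 symbol had a gene ID listed in the RefSeq table of assembly GRCm38.p6, which was used for names only. These probes named 17711 genes. Each gene was represented by the probe with the highest mean over all 8 arrays. The 9494 genes whose probe was detected on at least 4 of the 8 arrays were tested.

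Surface and crypt base were compared with limma 3.58.1 in R 4.3.3, with the replicate number as a fixed block, lmFit and eBayes with default settings, a two-sided test and Benjamini-Hochberg adjustment at 0.05. Random-effect blocks used statmod 1.5.0. The fit left 3 residual degrees of freedom and had 3.09 prior degrees of freedom. Changes are given as the log2 value at the surface minus that at the crypt base, with the standard error of the fit. Background correction and quantile normalization of raw signals had been planned. The deposited values were already normalized, so they were tested as deposited. The labels do not state that the replicate number marks the mouse. Across genes, which are not independent replicates, the deviations of same-numbered samples from their group means correlated at r = 0.45 for number 1, 0.39 for number 2, -0.04 for number 3 and 0.48 for number 4. For samples of unlike number r ranged from -0.49 to 0.31. It was 0.31 for surface 2 with crypt base 3 and 0.27 for surface 3 with crypt base 2, both above the value for number 3. The pairing therefore rests on the design text and not on the check for every number, and results of the fit without the block are given beside those of the blocked fit where they differ. Where same-numbered samples are called a pair, this limit applies.

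The 41 gene lists and the rule for the genes named in the text were fixed before the data were examined, and so were the alternatives other than those stated to have been added. The rule took the 12 genes with the largest change in each direction among those past the threshold that moved the same way in all 4 pairs, leaving out clone-named genes and probes naming several genes. It also took every claudin above background, the 4 factors in the series title, 2 to 4 examples per list with the largest changes past the threshold and the largest opposite change, and the brightest members of the lists of other cell types. A further 6 genes were chosen after their values were seen and are named as such. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 41 lists. Camera compares a list with the other genes tested. Camera with an estimated correlation was run beside it, and so was fry, which tests whether the genes of a list move on balance in a direction and compares them with no other genes. The alternatives changed the block, the normalization, the background correction, the filter, the choice of probe, the array weights, the variance model, a 1.5-fold limit and the replicates included. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

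The fit was tested on simulated data with independent errors, in which 200 of the 9494 genes were changed. In the same data the 67 genes of the oxidative phosphorylation list were shifted by -0.5. They count neither among the 200 nor among the unchanged genes. With 4 pairs, 52.2% of genes changed by 0.5 on the log2 scale were recovered with the right sign, 98.5% of those changed by 1 and 100% of those changed by 2, and 8 unchanged genes were called. With 3 pairs the shares were 14.9%, 97.0% and 100%, and 8 unchanged genes were called. The shifted list was called by camera at 4 pairs with the preset correlation (adjusted p = 6.4e-55) and with the estimated correlation (adjusted p = 0.0104). At 3 pairs it had an adjusted p of 1.2e-54 and 0.178. The simulated errors were independent and had the moderated variances of the full fit, so these shares need not hold for the data. In the data, leaving out a replicate gave from 0 genes higher and 0 lower (without replicate 1) to 1157 and 1146 (without replicate 2).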

Results

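Transcript levels were measured on Illumina bead arrays in epithelium captured from the surface and from the crypt base of the mouse distal colon. Some markers of smooth muscle, leukocytes and fibroblasts were far above background in both regions. Mean log2 signals at the crypt base and the surface were 12.59 and 11.75 for Acta2, 11.46 and 11.27 for Laptm5 and 10.38 and 10.00 for Dcn. A change may therefore lie in the epithelium or in other cells captured with it, which were not separated. Each group held 4 samples, numbered 1 to 4, and each of 4 mice had given both kinds of sample. The comparison asks how the epithelium differs between the crypt base and the surface, and the series title directs it to claudins, which are proteins of the tight junction, and to the factors Hopx, Klf4, Tcf7l2 and Hnf4-alpha. Correlations between arrays, taken across genes, which are not independent replicates, ranged from 0.916 to 0.978 within the surface group. They ranged from 0.955 to 0.982 within the crypt base group and from 0.884 to 0.977 between the groups. The sample surface 4 stood apart, with 199 probes more than 2 log2 units from the median of the other 7 arrays, 184 of them lower. The other arrays had 6 to 34 such probes.

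**Figure D1:**
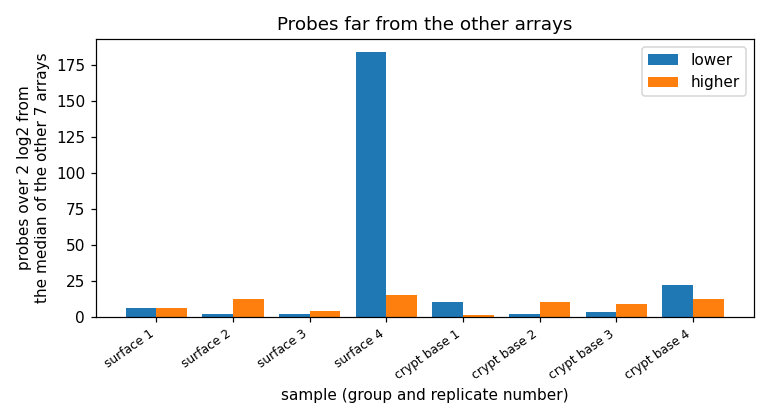
Number of probes per sample (bars, y axis) that lie more than 2 log2 units below or above the median of the other 7 arrays, for each of the 8 samples on the x axis. The sample surface 4 has 184 such probes below and 15 above, and crypt base 4 has 22 below and 12 above.

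At the surface, markers of mature colonocytes were among the genes that rose most, and genes of cell division were among those that fell most. The largest rise was that of Lama3, a laminin chain of the basement membrane, by 2.11 ± 0.18 on the log2 scale (SE, n = 4 pairs), which is 4.30-fold (adjusted p = 0.00739). Aqp8, a water channel, rose by 2.05 ± 0.22, the acute-phase gene Saa1 by 2.00 ± 0.15, the protease gene Prss30 by 1.99 ± 0.23 and Car4, a membrane-bound carbonic anhydrase, by 1.97 ± 0.22. The largest fall was that of Cdca7, a cell division cycle gene, with a change of -1.65 ± 0.22, which is 3.14-fold lower (adjusted p = 0.00881). Cldn2, a pore-forming claudin, changed by -1.62 ± 0.21, Cps1, the mitochondrial carbamoyl phosphate synthetase, by -1.57 ± 0.15, Nusap1, a spindle protein gene, by -1.50 ± 0.24 and Ttr, the transthyretin gene, by -1.48 ± 0.19.

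Among the 9494 genes tested, 1147 were higher and 963 were lower at the surface at an adjusted p of 0.05, which together is 22.2% of the genes. Of these 2110 genes, 2102 moved the same way in all 4 pairs. The change reached 2-fold in 210 of the genes that rose and 61 of those that fell. Also among the 12 largest rises were Bnip5, Upp1 (uridine phosphorylase), Ceacam20, Slc20a1 (a phosphate transporter), Clca4a, Cyp2d34 and Rdh9, with changes from 1.85 to 1.94. Also among the 12 largest falls were Nop58, H2ac15, H2ac12, H2ac6, Gsta3, Cdca3 and H2ac23, with changes from -1.65 to -1.44. The H2ac genes encode near-identical H2A histones whose transcripts a probe may not tell apart, and 2 other probes of H2ac6 had changes above 0, up to 0.43. The probes of Nop58, H2ac15 and H2ac6 are among the 184 probes that were low in surface 4, where that of Nop58 had a log2 signal of 4.54, under background. The Nop58 probe nevertheless had a detection p under 0.05 on all 8 arrays. Another probe of Lama3 had a change of 0.12, and one of Slc20a1 had a change of 0.00717. Of the 136 genes named here as passing the test, 41 had more than 1 probe above background, and in 28 of these another probe had under 50% of the change given, 6 with the opposite sign. Such weaker probes are given by gene for only some of them. Not repeated below are other probes of Mep1b (0.31), Gsdmd (0.39), Irf1 (0.47), Cxadr (0.26), Kcnq1 (-0.39) and H2-K1 (0.52).

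Without the replicate block 688 genes were higher and 579 lower, 1228 genes were called in both fits, and 48 of the 136 genes named here as passing the test did not pass. Of the genes above, these were Nop58 (adjusted p = 0.189), H2ac15 (0.139), H2ac12 (0.0983), H2ac6 (0.101), H2ac23 (0.0946) and Gsta3 (0.0561). Leaving out replicate 1 ended every call in limma, and this holds for every gene named below. The lowest adjusted p was then 0.05002, with 0 genes called and 2512 at an unadjusted p under 0.05. All 2110 genes kept their sign, but it could not turn in the 2102 that moved the same way in all 4 pairs. The counts were 1157 and 1146 without replicate 2, 639 and 404 without replicate 3 and 580 and 219 without replicate 4. Of the 136 named genes 7 did not pass without replicate 2, 41 without replicate 3 and 49 without replicate 4. These losses are given below for only some of the genes.

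Claudins moved in both directions between crypt base and surface. Cldn4 (gene ID 12740) rose from a log2 signal of 8.02 ± 0.45 (SD, n = 4) at the crypt base to 9.48 ± 0.49 at the surface, a change of 1.46 ± 0.09 (SE), or 2.75-fold (adjusted p = 0.00739). Cldn23 rose by 1.21 ± 0.15, Cldn3 by 1.04 ± 0.11 and Cldn7 by 0.68 ± 0.07. Cldn2 (gene ID 12738) fell from 9.04 ± 0.23 to 7.42 ± 0.54, which was 3.07-fold lower at the surface (adjusted p = 0.00881). Cldn5, known from blood vessel walls, changed by -0.63 ± 0.12 and Cldn15, which forms cation channels, by -0.42 ± 0.11. Of the 14 genes of the claudin list that were tested, 4 rose and 3 fell, and 5 rose and 3 fell adjusted over the list alone. The series title names claudins, so these counts are not independent evidence of a direction. The 7 that did not pass had changes of 0.28 (Cldnd1), -0.19 (Cldn12), 0.15 (Cldn34b4), 0.17 (Cldn9), -0.03 (Cldnd2), 0.00220 (Cldn19) and -0.00169 (Cldn10), and the signs of Cldn19 and Cldn10 changed with the scaling. Crypt base and surface means were near background for Cldn19 (5.62 and 5.63), Cldn34b4 (5.59 and 5.74) and Cldn9 (5.94 and 6.11). They were 8.71 and 8.52 for Cldn12. Signals under background were those of Cldn10 in surface 4 (5.36) and Cldn15 in surface 1 and surface 4 (5.31 and 5.43). Small changes in these dim genes may be understated and do not show equal levels. Cldnd1 and Cldnd2 are claudin domain genes and not claudins in the narrow sense. Camera gave no call for the list (median change 0.07, adjusted p = 0.236), and fry gave an adjusted p of 0.0165. Cldn5 and Cldn15 did not pass without the block (adjusted p = 0.0565 and 0.240), nor did Cldn15 without replicate 3 (0.0931) or replicate 4 (0.140).

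**Figure D2:**
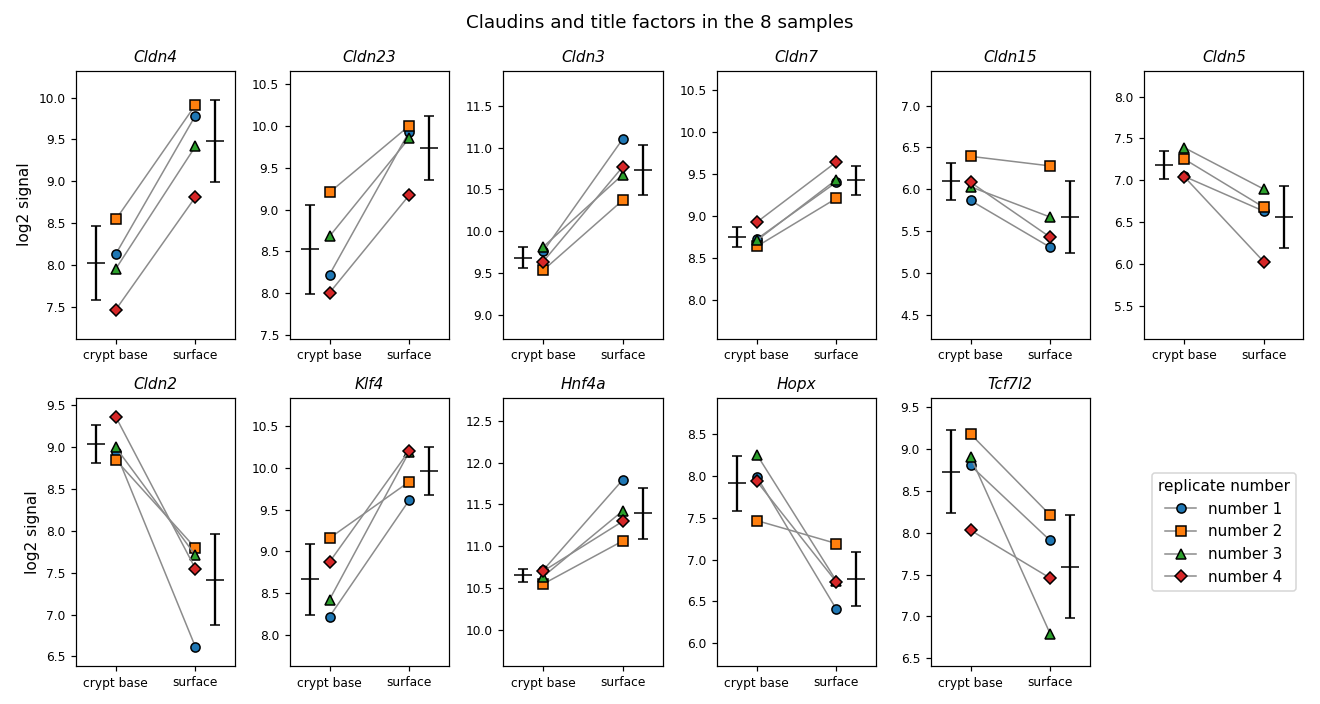
Log2 signal (y axes, spanning the same number of units in every panel) at the crypt base and the surface for the 7 claudins that passed the test and the 4 title factors, with a line joining same-numbered samples and bars for the mean ± SD of 4 samples. Cldn4, Cldn23, Cldn3, Cldn7, Klf4 and Hnf4a are higher at the surface in all 4 pairs, and Cldn15, Cldn5, Cldn2, Hopx and Tcf7l2 are lower in all 4.

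Other junction genes rose more often than they fell. Of 16 tight junction genes other than claudins, 7 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone. Ocln, which encodes occludin, rose by 0.91 ± 0.16, Ildr1, of tricellular contacts, by 0.84 ± 0.09 and Cxadr, a virus receptor at the junction, by 0.81 ± 0.16, whereas Ybx3, whose product binds ZO-1, changed by -0.32 ± 0.08. The list shifted upwards (median change 0.37, adjusted p = 0.000732, and adjusted p = 0.426 with an estimated correlation). Of 16 genes of adherens junctions and desmosomes, 7 rose and 0 fell, and 8 rose and 0 fell adjusted over the list alone. The envoplakin gene Evpl rose by 0.94 ± 0.18, the desmoglein gene Dsg2 by 0.83 ± 0.14 and the plakoglobin gene Jup by 0.71 ± 0.10, and this list shifted upwards too (median change 0.33, adjusted p = 0.00176, and adjusted p = 0.426 with an estimated correlation). Other probes of Ildr1, Dsg2 and Jup had changes down to 0.01, -0.26 and -0.00151. Over the 3 junction lists 22 genes passed the test, against 13 without the replicate block, where Cxadr did not pass (adjusted p = 0.0514). The count was 0 without replicate 1 and 12 without replicate 4.

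The 4 factors of the series title all differed between the regions. Klf4 (gene ID 16600), a factor of differentiated epithelium, rose from 8.67 ± 0.43 (SD, n = 4) to 9.96 ± 0.29, a change of 1.29 ± 0.17 (2.44-fold, adjusted p = 0.00922). The weakest of the 3 Klf4 probes above background had a change of 0.47, and the probe used had a detection p under 0.05 on 6 of the 8 arrays, with log2 signals of at least 8.22. The nuclear receptor gene Hnf4a (gene ID 15378) rose from 10.65 ± 0.08 to 11.39 ± 0.30, a change of 0.74 ± 0.11 (adjusted p = 0.0111). Hopx (gene ID 74318), a homeodomain-only gene, went from 7.91 ± 0.33 to 6.77 ± 0.32, a change of -1.14 ± 0.22 (2.21-fold lower, adjusted p = 0.0194). Tcf7l2 (gene ID 21416), a transcription factor of the Wnt pathway, went from 8.73 ± 0.49 to 7.59 ± 0.62, a change of -1.14 ± 0.25 (2.20-fold lower, adjusted p = 0.0251). Of the 4 factors 2 rose and 2 fell, also adjusted over the list alone, and as the study named them, this is not independent evidence. Their median and mean change were -0.20 and -0.06, while camera's direction was up (adjusted p = 0.810). Tcf7l2 did not pass without the block (adjusted p = 0.0595) or without replicate 2 (0.0525), and Hopx did not pass without replicate 3 (0.0653) or replicate 4 (0.0570).

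Of 21 other intestinal transcription factors, 6 rose and 1 fell, also adjusted over the list alone. Mxd1, a Myc antagonist, rose by 1.68 ± 0.20, the bile acid receptor gene Nr1h4 by 0.85 ± 0.10 and the vitamin D receptor gene Vdr by 0.74 ± 0.16, and Gata6 changed by -0.38 ± 0.10. The list gave no call (median change 0.00465, adjusted p = 0.125) but gave one without replicate 4 (0.0184), and Gata6 did not pass without the block (0.127). Vdr did not pass without replicate 3 (0.0680) or replicate 4 (0.0799), nor did Gata6 without replicate 2 (0.0731) or replicate 4 (0.153). Without 2 members whose probes were low in surface 4 the list median was 0.19.

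Genes of proliferation and of ribosome production fell more often than they rose at the surface. In the cell cycle list of 22 genes 0 rose and 17 fell, and 0 rose and 19 fell adjusted over the list alone. Nusap1 and Cdca3 changed by -1.50 ± 0.24 and -1.46 ± 0.27 and the mitotic kinase gene Plk1 by -1.31 ± 0.28, and the list shifted downwards (median change -0.94, adjusted p = 2.34e-08, and adjusted p = 0.426 with an estimated correlation). In the DNA replication list of 34 genes 0 rose and 22 fell, and 0 rose and 27 fell adjusted over the list alone. Uhrf1, which maintains DNA methylation, changed by -1.34 ± 0.27 and the replicative helicase genes Mcm5 and Mcm4 by -1.27 ± 0.32 and -1.20 ± 0.20, with a downward shift of the list (median change -0.58, adjusted p = 3.79e-10, and adjusted p = 0.426 with an estimated correlation). In the ribosome biogenesis list of 28 genes 0 rose and 17 fell, and 1 rose and 23 fell adjusted over the list alone. Besides Nop58, Gar1 and Fbl, of small nucleolar ribonucleoproteins, changed by -1.22 ± 0.20 and -0.95 ± 0.15, and the list shifted downwards (median change -0.46, adjusted p = 2.25e-08, and adjusted p = 0.426 with an estimated correlation). Of 50 cytosolic ribosomal protein genes 0 rose and 28 fell, and 0 rose and 39 fell adjusted over the list alone. Rplp0, Rpl22 and Rpl27a changed by -0.99 ± 0.17, -0.98 ± 0.15 and -0.96 ± 0.16. The other probe changed by -0.36 for Rplp0 and by -0.17 for Rpl27a. The list shifted downwards (median change -0.63, adjusted p = 2.10e-12, and adjusted p = 0.426 with an estimated correlation). Each of these lists fell least in pair 2. There the list median was -0.21 for the cell cycle, -0.13 for DNA replication, -0.19 for ribosome biogenesis and -0.17 for ribosomal proteins. Smooth muscle markers had a median change of -0.80 in the comparison of surface and crypt base. By fry, which tests a list against no change and not against other genes, the adjusted p was 0.0580 for the cell cycle list, 0.0535 for DNA replication and 0.0565 for ribosomal proteins. In limma, Plk1 (adjusted p = 0.0799), Mcm5 (0.105) and Nop58 (0.103) did not pass without replicate 3. Without replicate 4, Plk1 (0.0713), Mcm5 (0.0996), Cdca3 (0.0521) and Uhrf1 (0.0579) did not pass.

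Of 12 colonic stem cell markers, 1 rose and 6 fell, and 1 rose and 7 fell adjusted over the list alone. Beside Cdca7, the receptor gene Lrig1 changed by -0.96 ± 0.15 and Smoc2 by -0.90 ± 0.17, whereas Prom1, which encodes a protein of membrane protrusions, rose by 0.96 ± 0.12. This list shifted downwards (median change -0.52, adjusted p = 0.0158, and adjusted p = 0.426 with an estimated correlation). Of 22 genes of Wnt signalling, 4 rose and 4 fell, also adjusted over the list alone. The Wnt feedback genes Rnf43 and Axin2 changed by -0.74 ± 0.10 and -0.72 ± 0.17 and the cyclin gene Ccnd1 by -0.63 ± 0.15 (-0.04 for its weakest probe), and the ephrin gene Efnb2 rose by 1.24 ± 0.14. Camera gave no call for the Wnt list (median change -0.07, mean change -0.00307, adjusted p = 0.924, with an upward direction by fry), and Axin2 and Ccnd1 did not pass without the block (adjusted p = 0.0733 and 0.0555).

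**Figure D3:**
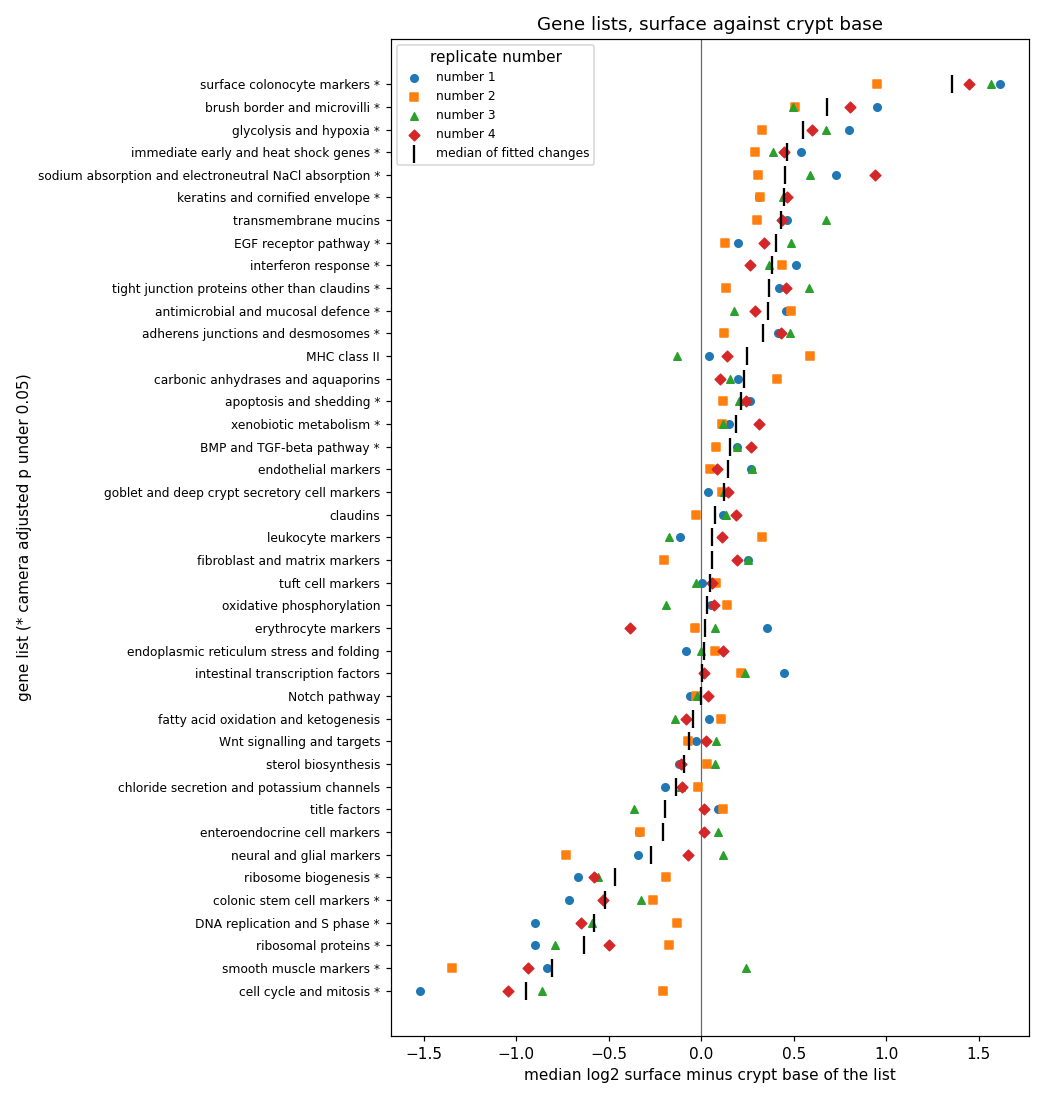
Median log2 difference, surface minus crypt base (x axis), over the tested members of each of 41 gene lists (y axis), with a symbol for each same-numbered pair and a black bar for the median of the fitted changes. An asterisk marks lists with a camera adjusted p under 0.05, surface colonocyte markers lie farthest to the right (1.35) and cell cycle genes farthest to the left (-0.94).

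Genes of the absorptive surface cell rose more often than they fell. Of 25 surface colonocyte markers 20 rose and 1 fell, and 22 rose and 1 fell adjusted over the list alone, the exception being Guca2b, the uroguanylin gene, with a change of -0.80 ± 0.20. That list had the largest upward shift (median change 1.35, adjusted p = 2.53e-12, and adjusted p = 0.426 with an estimated correlation). In the sodium absorption list of 19 genes 10 rose and 0 fell, and 10 rose and 1 fell adjusted over the list alone. The sodium-proton exchanger genes Slc9a3 and Slc9a2 rose by 1.67 ± 0.25 and 1.61 ± 0.19 and Atp12a, a proton-potassium pump, by 1.64 ± 0.17, with an upward shift of the list (median change 0.45, adjusted p = 0.000338, and adjusted p = 0.426 with an estimated correlation). Without 2 members whose probes were low in surface 4 the median was 1.04. In the brush border list of 23 genes 16 rose and 1 fell, and 17 rose and 1 fell adjusted over the list alone. The meprin genes Mep1a and Mep1b rose by 1.59 ± 0.16 and 1.54 ± 0.14 and the plastin gene Pls1 by 1.58 ± 0.17, while the peptidase gene Dpp4 changed by -0.70 ± 0.14, with 0.07 for its other probe. The brush border list shifted upwards (median change 0.68, adjusted p = 2.35e-08, and adjusted p = 0.426 with an estimated correlation). Slc9a3 and Guca2b did not pass without the block (adjusted p = 0.118 and 0.0513).

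Genes of chloride secretion moved in both directions. Of 10 tested, 2 rose and 3 fell, also adjusted over the list alone. The potassium channel genes Kcnn4 and Kcnq1 changed by -1.18 ± 0.19 and -1.004 ± 0.208 and the chloride channel gene Cftr by -0.999 ± 0.169, with 0.11 for its other probe, while Clcn2, another chloride channel gene, rose by 1.13 ± 0.08. Camera gave no call (median change -0.14, adjusted p = 0.737), and fry's direction was up (adjusted p = 0.729). Of 12 carbonic anhydrase and aquaporin genes 4 rose and 1 fell, also adjusted over the list alone. Car1 rose by 1.71 ± 0.24, besides Aqp8 and Car4, and Aqp1 changed by -1.10 ± 0.17, with no call by camera (adjusted p = 0.193) and one by fry (0.0116). Of 3 transmembrane mucin genes 2 rose and 0 fell, also adjusted over the list alone, Muc13 by 0.51 ± 0.10 and Muc1 by 0.43 ± 0.12, with a list adjusted p of 0.158 by camera and 0.0389 by fry. Of 27 goblet and deep crypt secretory cell markers 5 rose and 3 fell, and 5 rose and 5 fell adjusted over the list alone. The trefoil factor gene Tff3 rose by 0.91 ± 0.09, and Clca1, Capn9 and Ramp1 changed by 0.98 ± 0.24, 0.87 ± 0.11 and -0.90 ± 0.24, with a list adjusted p of 0.236 by camera and 0.0389 by fry. Car1 (0.0670), Muc13 (0.123), Clca1 (0.179), Capn9 (0.124) and Ramp1 (0.209) did not pass without the block.

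Genes of glycolysis and hypoxia and of xenobiotic metabolism rose more often than they fell. Of 20 genes of glycolysis and hypoxia 14 rose and 0 fell, and 15 rose and 0 fell adjusted over the list alone. The oxygen sensor gene Egln3 rose by 1.64 ± 0.20, Ankrd37 by 1.46 ± 0.20 and the glucose transporter gene Slc2a1 by 1.18 ± 0.17, with an upward shift of the list (median change 0.55, adjusted p = 4.02e-07, and adjusted p = 0.426 with an estimated correlation). Of 26 genes of xenobiotic metabolism 8 rose and 1 fell, and 10 rose and 3 fell adjusted over the list alone. The cytochrome P450 genes Cyp3a13, Cyp4f14 and Cyp2s1 rose by 1.56 ± 0.16, 1.44 ± 0.13 and 0.99 ± 0.21, and the glutathione transferase gene Gstm1 changed by -0.98 ± 0.19. The xenobiotic list shifted upwards (median change 0.19, adjusted p = 0.0464, and adjusted p = 0.426 with an estimated correlation), with an adjusted p of 0.100 without the block, 0.0532 without replicate 1 and 0.0836 without replicate 2. Ankrd37 (0.0761), Cyp4f14 (0.0704) and Cyp2s1 (0.0769) did not pass without the block.

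Of 67 genes of oxidative phosphorylation 4 rose and 3 fell, and 2 rose and 2 fell adjusted over the list alone. Ndufa6, Uqcrb and Cox5a changed by 0.66 ± 0.11, 0.51 ± 0.14 and 0.44 ± 0.09 and Ndufa4 by -0.66 ± 0.08, with a median of 0.03 and a mean of -0.03 over the list (adjusted p = 0.774, and 0.0397 without replicate 3). The probes of 2 members are among the 184 that were low in surface 4, and without these members the mean was 0.02. Of 19 genes of fatty acid oxidation and ketogenesis 1 rose and 2 fell, and 0 rose and 2 fell adjusted over the list alone. Bdh1, which makes ketone bodies, and Acaa2 changed by -0.56 ± 0.10 and -0.55 ± 0.12 and Etfa by 0.34 ± 0.09, with 0.03 for the other probe of Acaa2 (list adjusted p = 0.810). Of 15 genes of sterol synthesis 2 rose and 2 fell, also adjusted over the list alone, with changes of -0.51 ± 0.10 for Mvd, -0.33 ± 0.09 for Nsdhl and 0.37 ± 0.09 for Msmo1 (list adjusted p = 0.774). Without the block Ndufa6 (0.0627), Uqcrb (0.0879), Cox5a (0.261), Acaa2 (0.0546), Etfa (0.324), Mvd (0.374), Nsdhl (0.214) and Msmo1 (0.685) did not pass.

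Genes of defence against microbes and of the interferon response rose more often than they fell. Of 27 antimicrobial and mucosal defence genes 11 rose and 1 fell, and 15 rose and 1 fell adjusted over the list alone. Saa2 rose by 1.80 ± 0.21 and Lypd8, which keeps flagellated bacteria from the epithelium, by 1.41 ± 0.17, and the cytokine gene Il33 changed by -0.65 ± 0.16, with an upward shift of the list (median change 0.36, adjusted p = 0.00116, and adjusted p = 0.426 with an estimated correlation). Of 15 interferon response genes 9 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone. Rsad2, Irf1 and Oasl1 rose by 1.46 ± 0.18, 1.29 ± 0.14 and 1.14 ± 0.12 and Bst2 changed by -0.50 ± 0.08, and the list shifted upwards (median change 0.38, adjusted p = 0.000351, and adjusted p = 0.426 with an estimated correlation). Of 9 MHC class II genes 0 rose and 0 fell, also adjusted over the list alone, with changes of 0.49 for H2-Ab1 and 0.50 for H2-Aa (list adjusted p = 0.211, and 0.0151 without replicate 3). Of 23 genes of apoptosis and shedding 10 rose and 0 fell, and 11 rose and 0 fell adjusted over the list alone. The gasdermin gene Gsdmd, whose product forms membrane pores, rose by 1.13 ± 0.12, the caspase gene Casp4 by 0.77 ± 0.13 and Trp53inp1 by 0.69 ± 0.13, and this list shifted upwards (median change 0.22, adjusted p = 0.000956, and adjusted p = 0.426 with an estimated correlation). Bst2 (0.413), Casp4 (0.145) and Trp53inp1 (0.0515) did not pass without the block. Without replicate 3, Il33 (0.0544), Bst2 (0.0507) and Trp53inp1 (0.0574) did not pass. Without replicate 4, Il33 (0.107), Bst2 (0.0528) and Trp53inp1 (0.0561) did not pass.

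Of 19 immediate early and heat shock genes 9 rose and 2 fell, and 12 rose and 2 fell adjusted over the list alone. Fos, Atf3 and Dusp1, which respond fast to stimuli, rose by 1.56 ± 0.25, 1.248 ± 0.144 and 1.11 ± 0.25, and the chaperone gene Hsph1 changed by -0.65 ± 0.15. Camera placed this list higher at the surface (median change 0.46, adjusted p = 0.000732, and adjusted p = 0.426 with an estimated correlation). Fos varied within each region, with an SD of 1.37 at the crypt base and 0.85 at the surface. Of 17 keratin and cornified envelope genes 8 rose and 0 fell, and 10 rose and 2 fell adjusted over the list alone. The transglutaminase gene Tgm3 rose by 1.67 ± 0.15, S100a14 by 1.31 ± 0.16 and the protease inhibitor gene Serpinb1a by 1.28 ± 0.13, with an upward shift of the list (median change 0.44, adjusted p = 0.00384, and adjusted p = 0.426 with an estimated correlation). Fos (0.177), Dusp1 (0.209) and Hsph1 (0.195) did not pass without the block.

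Genes of several signalling pathways differed too. Of 24 BMP and TGF-beta pathway genes 8 rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone. Skil, Id1 and Id2 rose by 0.68 ± 0.13, 0.67 ± 0.18 and 0.64 ± 0.13 and Smad4 changed by -0.45 ± 0.07, with a small upward shift of the list against the other genes (median change 0.15, adjusted p = 0.0445, and adjusted p = 0.572 with an estimated correlation) and a fry adjusted p of 0.157 against no change. Of 11 EGF receptor pathway genes 3 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone. The feedback inhibitor gene Errfi1 rose by 1.26 ± 0.21, Dusp6 by 0.76 ± 0.21 and Erbb2 by 0.66 ± 0.10, Lrig1 fell, and the list shifted upwards against the other genes (median change 0.40, adjusted p = 0.0445, and adjusted p = 0.524 with an estimated correlation), with a fry adjusted p of 0.0948 against no change. Of 13 Notch pathway genes 1 rose and 2 fell, also adjusted over the list alone, with changes of 0.48 ± 0.11 for Numb (0.05 for its weakest probe) and -0.53 ± 0.10 for Notch1 (list median 0.000985, mean -0.06, adjusted p = 0.774). Of 21 genes of endoplasmic reticulum stress and folding 2 rose and 1 fell, also adjusted over the list alone, with changes of 0.59 ± 0.11 for Dnajb9, 0.43 ± 0.10 for Ddit3 and -0.50 ± 0.11 for Ern2 (list adjusted p = 0.698). The BMP list did not pass without replicate 1 (0.0532), 3 (0.0772) or 4 (0.0710), nor the EGF receptor list without the block (0.124) or without replicate 1 (0.0532) or 3 (0.0664). Without the block Id1 (0.104), Smad4 (0.118), Dusp6 (0.310), Numb (0.101), Notch1 (0.0574), Dnajb9 (0.150) and Ern2 (0.187) did not pass.

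Among markers of other cell types, the smooth muscle list was lower at the surface. Of its 14 genes 0 rose and 0 fell, also adjusted over the list alone, and the list shifted downwards against the other genes (median change -0.80, adjusted p = 0.00177, and adjusted p = 0.524 with an estimated correlation), with a fry adjusted p of 0.169 against no change. Its brightest members had log2 signals of 12.59 ± 0.67 (SD, n = 4) at the crypt base and 11.75 ± 1.01 at the surface for Acta2, 12.20 ± 1.04 and 10.96 ± 1.49 for Actg2, and 11.03 ± 0.84 and 10.50 ± 0.74 for Mylk. The Actg2 probe is among the 184 that were low in surface 4. The list median was lower at the surface in pairs 1, 2 and 4 (-0.83, -1.35 and -0.94) and higher in pair 3 (0.24). Of 24 fibroblast and matrix genes 2 rose and 2 fell, and 2 rose and 1 fell adjusted over the list alone (median 0.06, mean -0.01, or 0.03 without 1 member low in surface 4, adjusted p = 0.737), and Igfbp7, Dcn and Col4a2 had changes of 0.17, -0.39 and 0.07. Of 14 endothelial genes 1 rose and 0 fell, also adjusted over the list alone, and Pecam1, Esam and Egfl7 had changes of 0.39, 0.16 and 0.16. The endothelial list had an adjusted p of 0.0767, which was 0.0484 without replicate 2 and 0.0318 without replicate 4. Of 19 leukocyte genes 0 rose and 1 fell, and 0 rose and 0 fell adjusted over the list alone, with a median of 0.06 and a mean of -0.03 (adjusted p = 0.774). The T cell gene Cd8b1 changed by -0.80 ± 0.17, with -0.0685 for its other probe and no call without replicate 3 (0.0624) or 4 (0.0667), and Laptm5 and Coro1a had changes of -0.19 and 0.07. Of 7 neural and glial genes 0 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.113, and 0.0184 without replicate 3), with changes of -0.69 for Snap25, -0.19 for Rtn1 and -0.31 for Uchl1. Of 3 erythrocyte genes 0 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.924), with changes of 0.02 for Hbb-bs, -0.06 for Hbb-bt and 0.11 for Hba-a1.

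Of 12 enteroendocrine genes 0 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.165, and 0.0484 without replicate 4). The peptide hormone gene Insl5 changed by -0.69 ± 0.17 and did not pass without the block (adjusted p = 0.0734), and Pyy and Chgb had changes of -0.34 and -0.17. Of 8 tuft cell genes 1 rose and 0 fell, and 0 rose and 0 fell adjusted over the list alone (list adjusted p = 0.698). Lrmp had a change of 0.39 ± 0.10 and did not pass without the block (0.0919), and Dclk1 and Spib had changes of -0.10 and 0.09. Of the 41 lists 20 shifted by camera with the preset correlation, and 0 shifted with an estimated correlation. Among those 20 the estimated correlation ranged from -0.03 (xenobiotic metabolism) to 0.75 (cell cycle), against the preset 0.01. It was 0.68 for DNA replication and 0.64 for ribosomal proteins. Where it is high, the preset treats genes that vary together as nearly independent, and its adjusted p overstates the evidence. Fry, which tests another question, called 18 lists.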

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

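The tests of detection calls, of other cell types, of the signs of the pairs and of the ribosomal list without replicate 4 were chosen only after the result was seen. A sample was picked out when its gap to the nearest of the other 3 samples of its group was large against the group's range. Of 338 groups of values examined, 17 had such a sample, and about 16.9 are due by chance at 1 in 20.

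The array of surface 4 had 199 probes far from the other arrays, against 6 to 14 on the other surface arrays, and 184 of them were lower. Judged by other probes, lower transcript levels are argued against only in 57 genes. These had another probe, outside the 184, detected on at least 4 arrays. Their other probes deviated in surface 4 by a median of 0.0098 (quartiles -0.28 to 0.22). Probes among the 184 were not counted as other probes, so a gene whose probes all fell could not enter this test. For genes outside the 57 the test therefore cannot decide. Signals lost or misassigned on that array remain a candidate explanation: 72.8% of the 184 probes (134 probes, exact Clopper-Pearson 95% interval 65.8% to 79.1%) had a detection p under 0.05 on all 8 arrays. Of those, 120 lay under background in surface 4 although detected there. For these 120 probes the value contradicts the detection call, which argues against the deposited value being the signal behind that call. Over the 184 probes the median was 4.66 in surface 4 against 8.04 on the other 7 arrays. Cox4i1, a subunit of cytochrome oxidase named after its values were seen, had a log2 value of 4.60 in surface 4 and 12.66 to 13.10 on the other arrays. Its probe had a detection p under 0.05 on all 8 arrays.

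Smooth muscle markers had a median change of -0.80 at the surface. A loss of every kind of non-epithelial tissue alike is argued against in these samples. The fibroblast, endothelial and leukocyte medians were 0.06, 0.14 and 0.06. Their pair medians ranged from -0.20 to 0.33, all above 50% of the smooth muscle list's median change (-0.40). The lowest bound of their 95% bootstrap intervals was -0.0972. That bootstrap drew genes, which vary together, and not mice, so it does not measure the spread between mice. The neural and glial list had a median of -0.27 and pair medians of -0.34, -0.73, 0.12 and -0.07, with the signs of the smooth muscle pairs (-0.83, -1.35, 0.24 and -0.94). An exact two-sided sign-flip test of the 4 smooth muscle pair medians gave p = 0.25 and decides nothing, since 4 pairs cannot give a p under 0.125. Tissue holding muscle and nerve taken along with the crypt base may account for the pattern, as may a difference between the regions, and neither was tested.

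Ribosomal protein genes had a median change of -0.63 at the surface. A trend with signal level is argued against, since 0 of 10000 random lists matched for expression had a median as low, with a range from -0.24 to 0.30. An effect of surface 4 alone is argued against too, since the median was -0.65 without replicate 4 and the pairs ranged from -0.90 to -0.17. A difference between the regions stays open as a hypothesis, found and tested on the same data.

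The score of surface 4 on the second principal component, which held 22.99% of the variance, was -18.3, and the other surface samples had 16.04 to 19.15. Crypt base 4 had 34 probes far from the other arrays, against 11 to 12 in the other crypt base samples. The score of crypt base 4 on the first component, which held 47.5%, was 7.99, and the other crypt base samples had 20.4 to 21.8. On that component surface 4 had -47.2, while surface 1, 2 and 3 had -15.1, 2.16 and -11.6. The rule did not pick out surface 4 there, and surface 2 was the surface sample nearest to crypt base 4. Upp1 had a log2 value of 9.51 in surface 2, below 11.13 to 11.39 in the others of that group. Plk1 had 8.18 in surface 2, above 7.59 to 7.64. Gsta3 had 7.95 in surface 4, above 6.75 to 6.95, and Ildr1 had 7.99 in surface 4, above 7.72 to 7.76. In crypt base 1, Dpp4 had 8.29, above 7.95 to 7.98, and Dnajb9 had 5.76, below 6.42 to 6.53. In crypt base 2, Cldn19 had 5.71, above 5.58 to 5.60, Muc1 had 6.12, above 5.74 to 5.79, and H1f2 had 12.34, above 11.53 to 11.63. In crypt base 3, Cldn9 had 5.73, below 6.00 to 6.02, and Mcm4 had 9.58, above the next at 9.05. In crypt base 4, Clcn2 had 7.26, above 6.97 to 6.99, and Bst2 had 7.97, below 9.002 to 9.205.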

How the results depend on the processing

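The settings added after the data were seen are the normexp corrections with offsets 16 and 50, the fit without the probes that dropped in surface 4, and the fits without the block that leave out 1 array. For the 136 named genes that passed, 1604 comparisons were made over 12 other processing settings: 1551 kept direction and side of the threshold, 53 lost the call and 0 reversed. The random-effect block, the variance model, the other filters and the fit without the probes that dropped in surface 4 leave a gene's change as it was. In those settings a sign could not turn. For the 30 that did not pass, 355 comparisons gave 12 gained calls and 10 changes of sign. The count of genes higher ranged from 1006 to 1402 and that of genes lower from 827 to 1398 over the 12 settings. Without the replicate block there were 688 higher, 579 lower and 13 junction genes. A treat test against a 1.5-fold change gave 0 higher and 0 lower by limma (329 and 117 at an unadjusted p under 0.05, lowest adjusted p 0.110). With an estimated correlation 0 of the lists shifted, against 17 to 22 in the other camera settings. Fry, which tests a list against no change, called 18. Leaving out a replicate gave 0 to 1157 higher, 0 to 1146 lower and 0 to 24 junction genes, the 0 being without replicate 1. Without the block, leaving out 1 array gave 349 to 815 higher and 243 to 643 lower, the lowest without crypt base 3. The cause was not tested for any of these.

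Of the 2110 genes that passed, 2107 kept their sign with the mean of probes. Among named genes the sign turned only for some that had passed no test, and the cause was not tested. With log2(signal + 16), the change was -0.000679 for Cldn19, 0.0134 for Cldn10 and -0.00969 for Hbb-bs. Cyclic loess gave -0.00371 for Cldn19, and normexp with offset 50 gave 0.0171 for Cldn10 and -0.00743 for Hbb-bs. The mean of probes gave 0.0216 for Cldn10 and -0.289 for Hbb-bs, and array weights gave -0.0332 for Hbb-bs and -0.0258 for Spib. Leaving out a replicate gave -0.0771 to 0.0131 for Cldnd2, -0.0521 to 0.0666 for Cldn19, -0.164 to 0.154 for Cldn10, -0.140 to 0.180 for Hbb-bs and -0.144 to 0.0519 for Hbb-bt. It gave -0.00319 to 0.251 for Hba-a1, -0.0518 to 0.296 for Col4a2, -0.398 to 0.0589 for Laptm5, -0.246 to 0.320 for Coro1a, -0.322 to 0.0545 for Rtn1 and -0.217 to 0.283 for Spib.

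Not run were neqc, since the deposited signals were already normalized, median scaling, which moves nothing in values of equal distribution, and a slide block, as no slide is given. The deposited matrix, planned as an alternative, was used for the tests instead. Signals near background limit the fold changes of 19 genes dim on all 4 surface arrays only and 32 dim on all 4 crypt base arrays only.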

Other observations

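The gene families in this part, and 6 genes named in it (H2-K1, H2-D1, H2-T23, H2ac18, H1f2 and H2bc4), were chosen only after their values were seen, while the tests on splits of the samples were planned. Of 13 genes tested with H2- symbols outside the class II list, taken as MHC class I by symbol alone, 8 rose at the surface and 0 fell. Their median change was 0.53 (camera adjusted p = 0.000104, and adjusted p = 0.217 with an estimated correlation), with the same counts under each other scaling tried. H2-K1 rose by 1.46 ± 0.11 (SE, n = 4 pairs, limma adjusted p = 0.00739), H2-T23 by 0.82 ± 0.10 and H2-D1 by 0.56 ± 0.10, and all 3 lost the call without replicate 1 (adjusted p = 0.05002, 0.0524 and 0.0684). Without the block H2-T23 and H2-D1 did not pass (adjusted p = 0.0840 and 0.157), nor did H2-D1 without replicate 3 (0.0545). Of 66 genes of mitochondrial ribosomal proteins tested, 0 rose and 19 fell (median change -0.28, camera adjusted p = 8.38e-07, and adjusted p = 0.356 with an estimated correlation), and other scalings gave 0 to 1 higher and 18 to 20 lower.

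Histone cluster genes of the H2A and H2B families were tested apart, and the difference between the families was not tested. Both families were chosen after their values were seen, so camera's adjusted p is no independent evidence. The probes of H2ac15 and H2ac6 are among the 184 that were low in surface 4. Of 11 H2A genes 2 rose and 5 fell (median change -1.40, camera adjusted p = 0.0224, and adjusted p = 0.426 with an estimated correlation). The 5 that fell did not pass without the block, with adjusted p from 0.0946 (H2ac23) to 0.139 (H2ac15). Of 11 H2B genes 5 rose and 1 fell (median change 0.27, camera adjusted p = 0.0224, and adjusted p = 0.356 with an estimated correlation), and each scaling tried gave these counts for both families. H2ac18 rose by 1.37 ± 0.16, H1f2 by 0.98 ± 0.14 and H2bc4 by 0.84 ± 0.15, and these did not pass without replicate 1 (adjusted p = 0.05002, 0.0573 and 0.0823), nor did H2bc4 without replicate 3 (0.0549) or replicate 4 (0.0504). These genes have near-identical copies, and which copy a probe reads is uncertain.

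Of the 35 splits of the 8 samples into 4 and 4, 1 split, the real one, gave as many genes in the fit with no block, with 1267 genes against a highest other of 0. That share is under 0.05 but does not exclude chance, since these splits ignore the pairing given in the design text. Every other split also mixes surface and crypt base samples within a group. In the fit with the block, 8 splits part all 4 pairs, which is too few for a share under 0.05, and the real split (1 split) gave 2110 genes against a highest other of 0.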
